A study of Mus musculus with 40 samples.

How the data were processed

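Gene expression was measured by RNA sequencing in 40 mouse libraries that form 10 groups of 4 replicates. Whole ear skin came from mice whose MrgprD neurons express the diphtheria toxin receptor (DTR), from mice carrying Cre alone, and from wild-type mice whose ears received 50 mM β-alanine or PBS daily for 2 days. Mast cells were sorted from DTR and Cre mice, or grown from the peritoneum and cultured 6 h with 4 mM glutamate or 48 h with 50 uM NS102, each with its vehicle. The design text gives diphtheria toxin to DTR and Cre mice for 3 to 4 weeks, whereas the treatment labels of the Cre samples list the acetone and olive oil vehicle alone, so whether the Cre mice received toxin was not settled. The skin samples are labelled Epidermal while the design text describes whole ear.

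The deposited table holds FPKM values, made by the authors with STAR and Cufflinks on genome build mm9 according to the submitters' processing notes, which give no versions. Its header does not name the unit, and the values behave as FPKM: decimals whose sum per library ranged from 117574 to 508485. Any scaling between libraries beyond FPKM, the annotation and the filters are not stated, and the labels describe single and paired end libraries without assigning them. The table has 23812 rows and 23304 distinct symbols, and a repeated symbol received a suffix (Hist1h2ao.1). It lists 0 mitochondrial genes. No counts or library sizes were used, so the depth is unknown and no counting interval can be given. Ratios of the lowest values (under 0.1 FPKM) between replicates lay within 0.03 on the log2 scale of ratios of whole numbers up to 6 for 50.6% to 76.9% of genes, against 25.1% by chance, which gave depths relative to replicate 1 of a group of 0.57 to 1.42. Within groups, Pearson correlations between libraries ranged from 0.9392 to 0.9987.

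Each of 5 comparisons set the 4 treated libraries against their own 4 controls. Values were taken as log2(FPKM + 1) without further scaling. Genes with at least 1 FPKM in at least 4 of the 8 libraries were tested with limma 3.58.1 in R 4.3.3 (moderated statistics with a mean-variance trend, two-sided) and adjusted by Benjamini-Hochberg over the genes tested. An adjusted p under 0.05 counted as past the test. Fold changes are treated over control, and fitted log2 changes of genes near 0 FPKM depend on the added 1. The ablation effect in sorted cells was set against that in skin by an interaction term over 16 libraries. For 4 pairs of comparisons, fold changes were correlated across genes, with 1000 relabellings of the libraries as the reference. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the remaining steps.

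Before the data were examined, 39 gene lists were fixed from general knowledge, covering mast cell genes, other cell types of skin and blood, and stress, metabolic and growth programmes. Lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks if a list's own genes move on balance to 1 side, were run beside it. The rule for naming genes was also fixed beforehand. It took, per comparison and direction, up to 10 genes with the largest log2 change among those past the test, with at least 5 FPKM in the higher group and no overlap between the groups. It added 8 genes (Mrgprd, Mrgprb2, Grik2, Cpa3, Mcpt4, Cma1, Tpsb2, Kit) whatever their p, and list members in order of p, and it left out predicted genes and small RNAs. The rule allowed up to 4 members per list. That 2 were taken, from lists called by camera with a member past the test, was decided after the values were seen. Of the genes so named, 2 are not reported here and were left out of the search for outlying libraries and of the named genes of the interaction, while the counts and gene lists keep them.

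The procedure was tested on simulated data made with each comparison's own spread, as moderated by limma. Genes were drawn independently of each other, so the check of the lists does not cover genes that vary together. Single changes were planted only in genes with a mean log2(FPKM + 1) of at least 3, so the recovery does not cover genes of lower expression. Of genes given a log2 change of 0.5, 1 and 2, it recovered 98.5%, 100% and 100% for skin ablation, 88.1%, 98.5% and 100% for β-alanine, 1.49%, 52.2% and 100% for sorted cells, 100%, 100% and 100% for glutamate, and 98.5%, 98.5% and 100% for NS102. The false share among calls was 4.78%, 2.55%, 2.86%, 8.26% and 6.6% in this order, so above 5% for glutamate and NS102, and 1 list without a planted change was called for β-alanine. With no change planted it made 0 calls. Other settings fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, median centring, quantile normalization, the replicate number as a block, a spread shared by groups of the same kind, limma without trend or with library weights, and each library left out. A setting meant for count data did not apply. After the data were seen, a correction for transcript length was added, along with median centring for the lists and fits without the DTR sorted libraries 3 and 4 and the NS102 libraries 3 and 4, whose total FPKM lay below the other replicates. Transcript lengths came from GENCODE M21 for 23390 genes, matched by symbol, and coordinates are those of the table (mm9). The cultured replicates are not stated to be separate cultures, so for them a p-value measures the spread between samples.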

Results

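Whole ear skin, sorted skin mast cells and cultured mast cells were profiled in 40 libraries, 4 per group. The list of mast cell identity and granule genes had a mean of library medians of 1.44 FPKM in Cre skin, 69.2 FPKM in sorted Cre cells and 111 FPKM in cultured cells after 48 h with vehicle. The basal keratinocyte list stood at 35.1 FPKM in Cre skin, 0.0444 FPKM in sorted Cre cells and 0 FPKM in the cultured vehicle cells. The macrophage and monocyte list was at 0.417 ± 0.249 FPKM in sorted Cre and 0.0633 ± 0.026 FPKM in sorted DTR cells (SD, n = 4). The red blood cell list was at 12.5 ± 24.9 FPKM and 0.00596 ± 0.00939 FPKM, a mean set by 1 of the 4 Cre libraries. Mrgprd and Grik2, the kainate receptor subunit that NS102 is known to block, lay below the expression filter in every comparison. The highest library reached 0.158 FPKM for Mrgprd and 1.154 FPKM for Grik2, both in sorted cells. Depth was unknown, and total FPKM ranged from 117574 to 508485. Values below are means ± SD of FPKM over 4 libraries per group.

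The first comparison asked what loss of MrgprD neurons, sensory fibres ending in the epidermis, did to ear skin. Mast cell transcripts were higher in DTR than in Cre skin. Mcpt4, a mast cell chymase (chromosome 14, 56678580 to 56681147), went from 30.6 ± 3.37 to 102 ± 9.58 FPKM (SD, n = 4 per group), and Cpa3, the mast cell carboxypeptidase (chromosome 3, 20115514 to 20142080), from 12 ± 1.5 to 36.7 ± 3.69 FPKM. Cma1, another chymase, went from 20.4 ± 3.44 to 50.8 ± 4.07 FPKM and Tpsb2, a tryptase, from 7.59 ± 0.678 to 19.6 ± 1.64 FPKM. Their log2 changes were 1.71 (SE 0.083, limma adjusted p = 5.55e-06), 1.54, 1.28 and 1.26, with all 4 DTR libraries above all 4 Cre libraries. Kit, the stem cell factor receptor, rose from 2.42 ± 0.351 to 3.44 ± 0.363 FPKM (adjusted p = 0.0191) and Mrgprb2, a mast cell receptor for basic secretagogues, from 1.68 ± 0.381 to 2.56 ± 0.214 FPKM (adjusted p = 0.0225). Of 19 tested members of the mast cell list, 14 rose, 0 fell and 5 did not pass, and 16 rose adjusted over the list alone. The list's median log2 change was 0.42 (camera adjusted p = 4.77e-12, adjusted p = 0.175 with an estimated correlation). Its library medians averaged 1.44 ± 0.236 FPKM in Cre, 3.05 ± 0.26 FPKM in DTR and 2.79 ± 0.374 FPKM in PBS skin. PBS skin, which had no ablation, thus lay near DTR skin, and it was not tested against either group. By sex-linked genes PBS skin was male, and Cre and DTR skin were female. Whether the Cre group was low or the DTR group high cannot be told apart here.

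Fat and muscle transcripts fell in the same skin. The muscle list had a mean of library medians of 130 ± 50.8 FPKM in Cre, 72.7 ± 10.6 FPKM in DTR and 220 ± 67.7 FPKM in PBS skin. For the adipocyte list these were 35.9 ± 3.89, 16.3 ± 3.15 and 47.5 ± 8.18 FPKM. Cre and PBS skin, both without ablation, thus also differed, though they differed in sex as well. A difference in the tissue taken cannot be told apart from an effect of the ablation here. Of 15 adipocyte genes 13 fell, 14 adjusted over the list alone. Fabp4, a fatty acid carrier, went from 413 ± 40.9 to 167 ± 13.7 FPKM and Adipoq, the adipocyte hormone adiponectin, from 44.5 ± 5.26 to 18.6 ± 1.56 FPKM (SD, n = 4 per group). Of 18 skeletal muscle genes 12 fell and 1 rose, 17 and 1 adjusted over the list alone. Pvalb, a calcium buffer of fast fibres, went from 127 ± 52.7 to 28.8 ± 8.03 FPKM and Myh4, a fast myosin, from 58.6 ± 20.6 to 14.6 ± 3.69 FPKM. Among 22 oxidative phosphorylation genes 8 fell, 15 adjusted over the list alone, as in Sdhb (78 ± 4.09 to 67.4 ± 2.16 FPKM) and Cox5b (328 ± 22.2 to 280 ± 7.75 FPKM). Among 30 cell cycle genes 9 rose and 1 fell, 17 and 1 adjusted over the list alone, as in Mcm2, a replication helicase subunit (3.96 ± 0.206 to 5.62 ± 0.515 FPKM), and Top2a (8.03 ± 0.741 to 10.2 ± 0.467 FPKM). Of 25 ribosomal protein genes 1 fell (Rplp0, 2397 ± 145 to 2049 ± 121 FPKM), 0 adjusted over the list alone. Camera adjusted p was 3.18e-16 for adipocyte, 4.75e-10 for muscle, 2.56e-08 for oxidative phosphorylation, 4.64e-06 for cell cycle and 1.46e-05 for ribosomal protein genes. With an estimated correlation the adjusted p was 0.175 for adipocyte genes and 0.709 for each of the other 4 lists. Some single calls ended in other settings. With a spread shared by the skin groups adjusted p was 0.0647 for Rplp0, 0.143 for Sdhb, 0.109 for Cox5b and 0.0883 for Top2a, and with quantile normalization 0.0619 for Sdhb and 0.0908 for Cox5b. The other 30 of 36 tested lists did not pass.

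Other large rises in DTR skin were in Ccl20, a chemokine for Ccr6-bearing cells (3.23 ± 1.39 to 9.27 ± 2.24 FPKM, SD, n = 4 per group), Cyp11a1, a steroidogenic enzyme that mast cells express (2.12 ± 0.449 to 5.49 ± 0.489 FPKM), and Neat1, a nuclear long noncoding RNA (273 ± 60.4 to 530 ± 29.1 FPKM). Alad, an enzyme of haem synthesis, rose from 9.06 ± 0.615 to 22.4 ± 2.18 FPKM and Hdhd3 from 2.37 ± 0.134 to 5.92 ± 0.962 FPKM. Both lie on chromosome 4, Alad at 62167017 to 62181097 and Hdhd3 at 62160087 to 62163234. In sorted Cre and DTR cells Alad was at 1.97 ± 0.492 and 2.04 ± 0.57 FPKM, and Hdhd3 at 0.429 ± 0.535 and 0.953 ± 0.373 FPKM. Psmc3ip on chromosome 11, looked at after values had been seen, was at 11.3 ± 0.313 FPKM in Cre and 4.68 ± 0.265 FPKM in DTR skin. That step is like the one from PBS to β-alanine skin (10.4 ± 0.792 to 4.34 ± 0.268 FPKM). Sorted Cre and DTR cells went the other way (0.419 ± 0.535 and 2.15 ± 0.977 FPKM). Whether the Cre and DTR mice also differed in stock was not tested, and such a difference would coincide with the ablation. The largest fall was in Cyp2g1 (65.4 ± 11 to 13.5 ± 11.7 FPKM). Lars2, a mitochondrial leucyl-tRNA synthetase, fell from 124 ± 12.7 to 37 ± 7.8 FPKM, Nnat from 16.3 ± 4.76 to 3.56 ± 0.664 FPKM and Hp, haptoglobin, from 33.9 ± 5.13 to 11.9 ± 3.22 FPKM. In all, 1719 of 12607 genes passed limma, 931 higher and 788 lower, and after median centring 811 were higher and 917 lower. In these groups 21.4% of genes had no overlap between the groups against 2.86% by chance. Leaving out Cre library 4 gave 947 genes, DTR library 1 gave 870, DTR library 2 gave 779 and DTR library 3 gave 996, and a spread shared by the skin groups gave 729. Fold changes followed transcript length (Spearman rho 0.317 over 12506 genes, which are not independent replicates). After correction for length the ribosomal protein call ended (median -0.018 in place of -0.11, adjusted p = 0.384). That of oxidative phosphorylation stayed (median -0.12 in place of -0.17, adjusted p = 3.91e-05), with 1 of 22 genes lower in place of 8. The adjusted p of Mrgprb2 was 0.0519 without Cre library 2, 0.053 without DTR library 1 and 0.0637 without DTR library 2, that of Kit 0.0553 without DTR library 2.

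**Figure D1:**
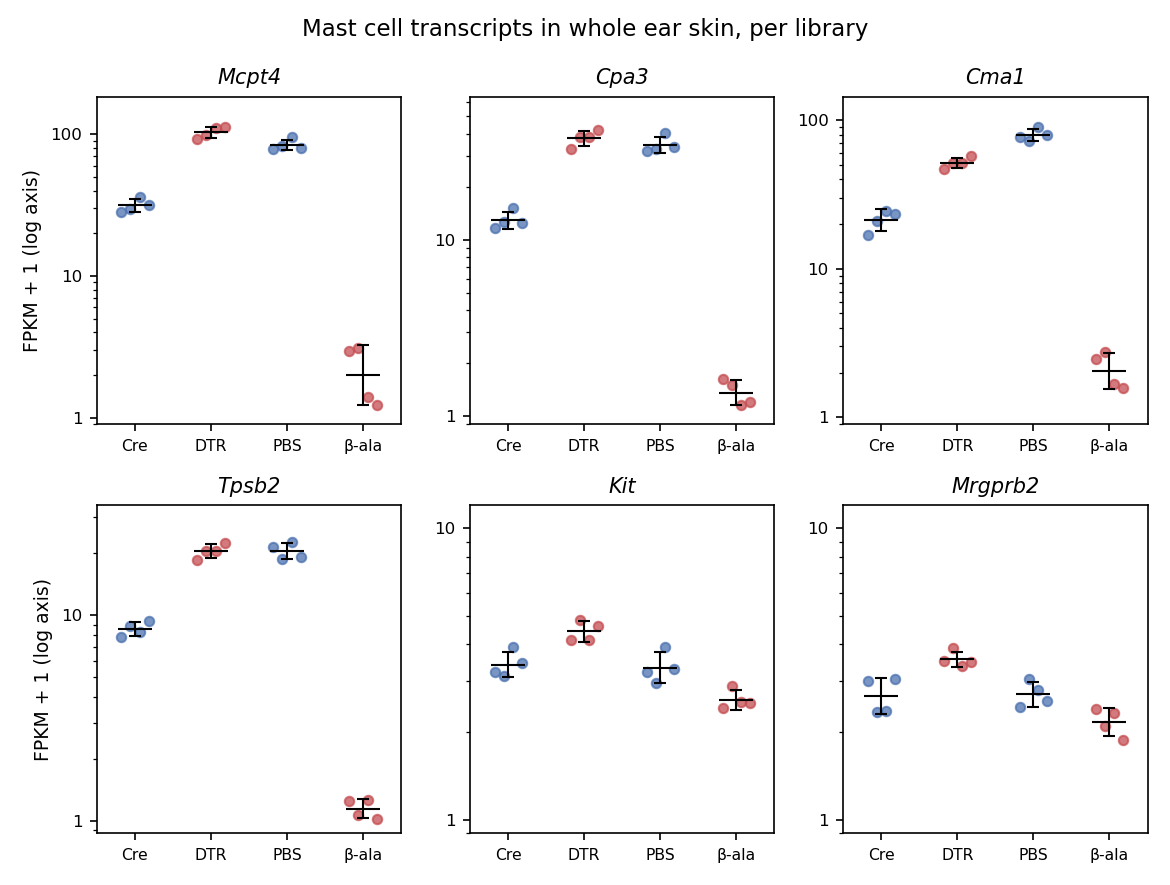
Each panel shows 1 gene in whole ear skin as FPKM + 1 on a log axis, with points for the 4 libraries of each group and a black bar for the mean ± SD of the log values. Mcpt4 averaged 30.6 FPKM in Cre and 102 FPKM in DTR skin, and 83.2 FPKM in PBS and 1.17 FPKM in β-alanine skin.

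The second comparison asked what β-alanine, a ligand of MrgprD, did to wild-type ear skin after 2 daily applications. Mast cell granule transcripts were close to absent in β-alanine skin. Mcpt2, a mast cell chymase, fell from 138 ± 21.8 to 0.401 ± 0.0909 FPKM (SD, n = 4 per group), Mcpt4 from 83.2 ± 7.7 to 1.17 ± 0.991 FPKM, Cma1 from 78.7 ± 7.87 to 1.12 ± 0.587 FPKM, Cpa3 from 33.6 ± 3.97 to 0.370 ± 0.226 FPKM and Tpsb2 from 19.5 ± 1.83 to 0.151 ± 0.123 FPKM. Their limma adjusted p ranged from 6.32e-10 (Mcpt2, log2 change -6.63, SE 0.11) to 5.86e-06 (Mcpt4, log2 change -5.40), and all 4 treated libraries lay below all 4 controls. Ctsg, cathepsin G, fell from 8.6 ± 1.42 to 0.131 ± 0.111 FPKM. Kit was at 2.34 ± 0.415 FPKM in controls and 1.58 ± 0.209 FPKM in treated libraries (adjusted p = 0.306) and Mrgprb2 at 1.7 ± 0.263 FPKM in controls and 1.17 ± 0.240 FPKM in treated libraries (adjusted p = 0.383), neither past the test. Reads of the neighbouring chymase genes on chromosome 14 can be shared, so the values of Mcpt2, Mcpt4 and Cma1 are uncertain relative to each other. In DTR skin, however, Mcpt2 was at 0.00853 FPKM beside Mcpt4 at 102.5 FPKM and Cma1 at 50.8 FPKM. Few reads of Mcpt4 or Cma1 were thus counted as Mcpt2 there.

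Of 20 tested mast cell list genes 10 fell and 0 rose, and 15 fell adjusted over the list alone, with a median log2 change of -1.0 (camera adjusted p = 1.68e-34, adjusted p = 0.0197 with an estimated correlation). Among 28 immediate early genes 2 fell, Fos from 10.3 ± 1.36 to 3.38 ± 0.395 FPKM and Egr1 from 24.2 ± 1.75 to 12.8 ± 1.44 FPKM (SD, n = 4 per group), and 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 8.73e-07, adjusted p = 0.0588 with an estimated correlation). Of 13 mast cell cytokine and chemokine genes 1 fell, adjusted over the list alone also 1: Xcl1, a chemokine better known from T and NK cells, went from 24.9 ± 3.91 to 9.31 ± 2.48 FPKM (camera adjusted p = 0.0399, adjusted p = 0.872 with an estimated correlation). Psmc3ip, a recombination cofactor, fell from 10.4 ± 0.792 to 4.34 ± 0.268 FPKM. Sdr39u1, the gene next to Cma1 on chromosome 14 (56516121 to 56519069), rose from 24 ± 0.722 to 49.5 ± 7.72 FPKM (log2 change 1.0, adjusted p = 0.0011).

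Camera called 8 further lists of which 0 members passed limma by themselves. Cell cycle genes (median log2 change -0.21, adjusted p = 1.03e-07) and red blood cell genes (-0.84, adjusted p = 1.05e-04) were lower relative to the other genes. Skeletal muscle (0.28, adjusted p = 3.33e-07), melanocyte (0.36, 3.53e-04), endothelial (0.061, 0.0102), adipocyte (0.14, 0.0109), interferon-stimulated (0.072, 0.0155) and basal keratinocyte genes (0.067, 0.0212) were higher. With an estimated correlation the adjusted p was 0.0798 for red blood cell, 0.701 for basal keratinocyte and 0.872 for the other 6 of these lists. Adjusted over the list alone, 4 red blood cell genes fell, 1 melanocyte gene rose and 1 fell, and 0 genes of the other 6 lists passed. In all, 27 of 12709 genes passed limma, 2 higher and 25 lower (4 and 24 after median centring), and 1247 had an unadjusted p under 0.05. A spread shared by the skin groups gave 130 genes, library weights gave 46, and without PBS library 1 the called lists were 7 in place of 11. The calls of adipocyte and interferon-stimulated genes ended after median centring, and that of basal keratinocyte genes after length correction (0.156). Those of endothelial genes (0.311) and of cytokines and chemokines (0.178) ended without β-alanine library 1.

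**Figure D2:**
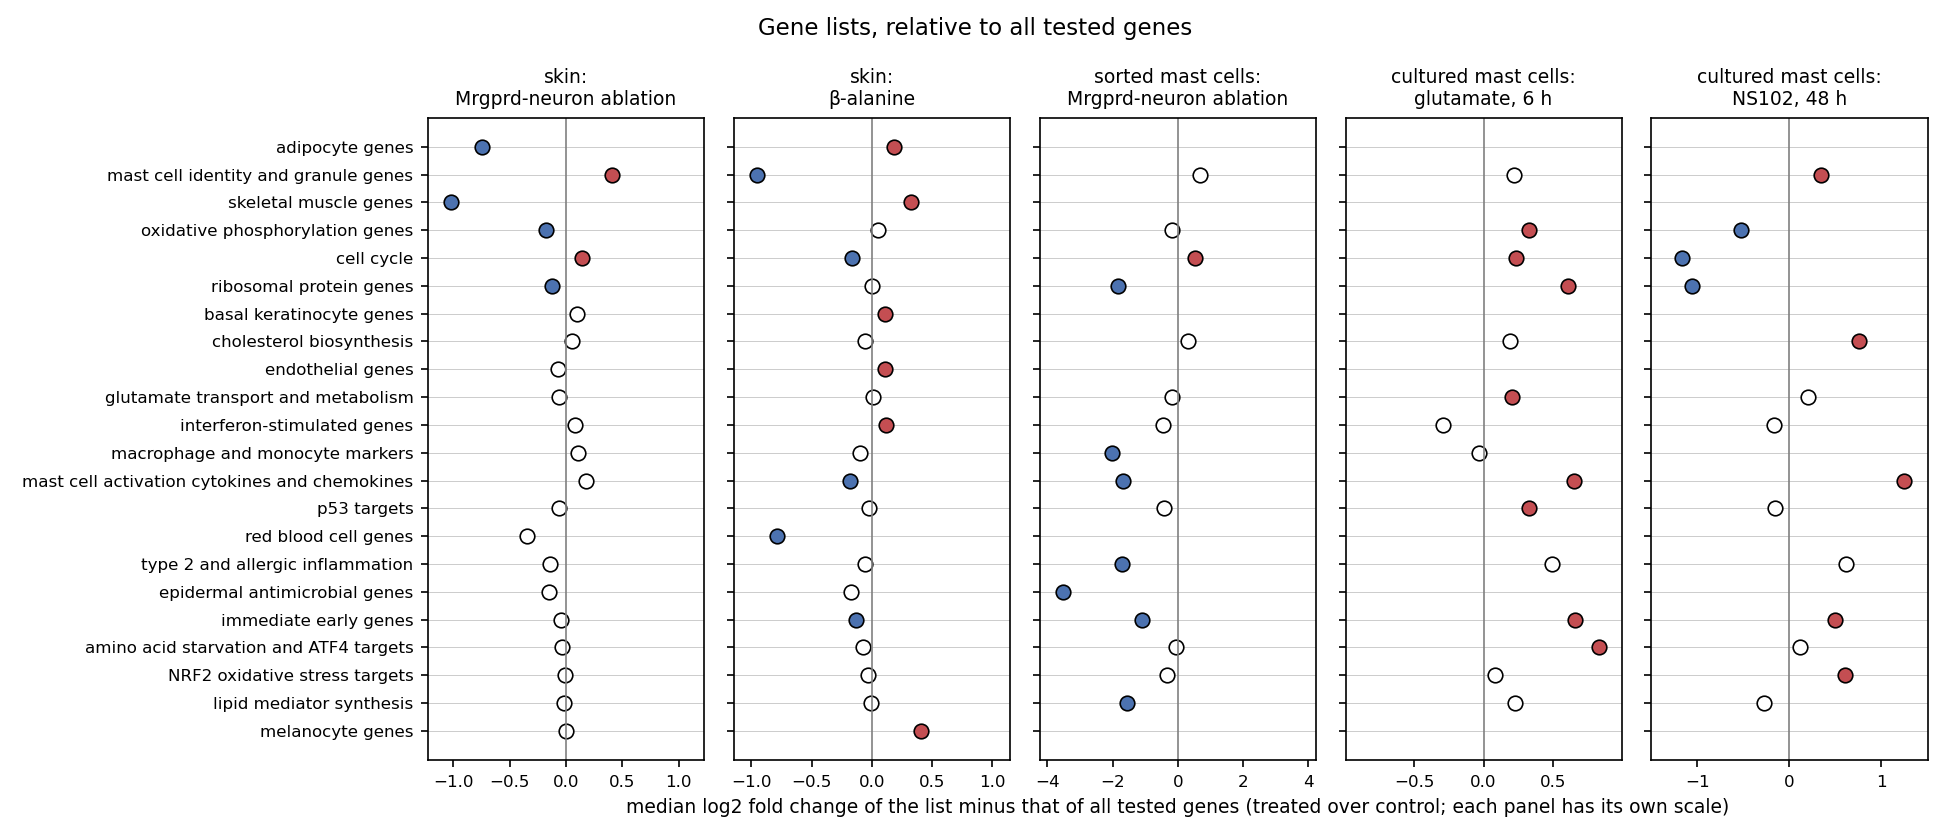
Each panel is 1 comparison, with the median log2 fold change of a list minus that of all tested genes on the x axis, for the 22 lists called at least in 1 comparison. Red and blue points mark lists called higher and lower by camera at the preset correlation, white points lists that did not pass, and lists with fewer than 5 tested members are not drawn, so that the mast cell list lies at 0.40 in DTR skin and -0.96 in β-alanine skin.

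The third comparison asked what the same ablation did to mast cells sorted from skin. Of the genes named beforehand, 6 mast cell genes were higher in DTR cells. Kit (chromosome 5, 75971011 to 76052746) rose from 47.6 ± 5.79 to 196 ± 47.6 FPKM (SD, n = 4 per group), Mrgprb2 from 44 ± 9.74 to 160 ± 29.3 FPKM, Cpa3 from 1891 ± 271 to 4352 ± 844 FPKM, Tpsb2 from 2729 ± 617 to 6478 ± 1649 FPKM, Mcpt4 from 1923 ± 429 to 3639 ± 950 FPKM and Cma1 from 3879 ± 892 to 7542 ± 1936 FPKM. The median log2 change of all genes was 0.13, and relative to it these genes changed by 1.86, 1.72, 1.06, 1.11, 0.78 and 0.82, with limma adjusted p from 1.06e-06 (Kit) to 0.0136 (Mcpt4). Other members fell, among them Mcpt8, a protease that mouse basophils make (343 ± 88.9 to 2.11 ± 0.531 FPKM), and Cdh1, E-cadherin (35.2 ± 6.14 to 0.112 ± 0.162 FPKM). Of 28 mast cell list genes 15 rose, 5 fell and 8 did not pass, 17 and 5 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0794). Adjusted p was 0.0592 for Mcpt4 and 0.0526 for Cma1 without Cre library 1, and 0.0528 and 0.052 without DTR library 2. With no expression filter it was 0.121 for Cpa3, 0.249 for Mcpt4, 0.363 for Cma1 and 0.184 for Tpsb2, and with quantile normalization 0.0929 for Cma1.

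Several chemokine transcripts that were abundant in sorted Cre cells were close to 0 in sorted DTR cells. Ccl3 (chromosome 11, 83461344 to 83462880), a chemokine for macrophages and T cells, went from 2372 ± 676 to 0.0116 ± 0.0233 FPKM (SD, n = 4 per group), Ccl4 from 3244 ± 832 to 2.02 ± 3.1 FPKM, Ccl6 from 2917 ± 760 to 0.0714 ± 0.0921 FPKM and Ccl9 from 414 ± 85.2 to 0.0744 ± 0.0485 FPKM. Of 12 cytokine and chemokine genes 8 fell and 0 rose, the same numbers adjusted over the list alone (camera adjusted p = 3.20e-08, adjusted p = 0.245 with an estimated correlation). Of 25 ribosomal protein genes 24 fell, 24 adjusted over the list alone, with a median log2 change of -1.84 relative to all genes (camera adjusted p = 8.32e-16, adjusted p = 0.429 with an estimated correlation), as in Rps19 (338 ± 62.5 to 61.9 ± 16.2 FPKM). Of 23 immediate early genes 13 fell, 13 adjusted over the list alone, as in Nfil3 (38.3 ± 8.98 to 0.330 ± 0.131 FPKM) and Jund (139 ± 39.7 to 5.6 ± 2.17 FPKM). Camera gave adjusted p = 1.73e-06 for the list, and adjusted p = 0.438 with an estimated correlation. Of 9 genes of lipid mediator synthesis 5 fell and 1 rose, 5 and 1 adjusted over the list alone, as in Alox15 (72.4 ± 15.7 to 0.0113 ± 0.0226 FPKM) and Alox5ap, the 5-lipoxygenase activating protein (324 ± 79.7 to 3.35 ± 0.991 FPKM). The camera adjusted p of the list was 3.43e-04, with adjusted p = 0.245 with an estimated correlation. Of 14 cell cycle genes 9 rose, 9 adjusted over the list alone, as in Mcm2 (0.641 ± 0.439 to 3.76 ± 1.23 FPKM) and Ccnb2 (0.179 ± 0.210 to 2.26 ± 0.801 FPKM). Here camera gave adjusted p = 0.00348, and adjusted p = 0.438 with an estimated correlation.

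Lists of other cells and of inflammation were also tested in sorted cells. All 5 tested genes of the epidermal antimicrobial list fell, 5 adjusted over the list alone (camera adjusted p = 9.74e-07, adjusted p = 0.0372 with an estimated correlation), and they include Pglyrp1, a granulocyte peptidoglycan receptor (107 ± 24.3 to 0.153 ± 0.129 FPKM, SD, n = 4 per group), and Slpi, a protease inhibitor of epithelia and leukocytes (37.6 ± 7.65 to 0.0413 ± 0.0476 FPKM). Of 5 type 2 inflammation genes 4 fell and 1 rose, 4 and 1 adjusted over the list alone, as in Ccr3, the eotaxin receptor of eosinophils and basophils (10 ± 3.67 to 0.0364 ± 0.0249 FPKM). The camera adjusted p of the list was 0.0176, with adjusted p = 0.438 with an estimated correlation. Of 7 macrophage and monocyte markers 4 fell and 1 rose, 4 and 1 adjusted over the list alone, as in Ccr2 (26.8 ± 10.3 to 0.0426 ± 0.0361 FPKM) and Itgam (6.06 ± 1.65 to 0.0429 ± 0.0456 FPKM). Here camera gave adjusted p = 0.0259, and adjusted p = 0.245 with an estimated correlation. Of 6 T and innate lymphoid cell markers 4 fell and 1 rose, the same numbers adjusted over the list alone, and the list was not called (camera adjusted p = 0.0794). The largest falls also held Ifitm1 (1740 ± 598 to 0.624 ± 0.444 FPKM), Cd7 (306 ± 57.1 to 0.0314 ± 0.0628 FPKM) and Plac8 (214 ± 56.8 to 0.0237 ± 0.0474 FPKM), and Defb40, at 134 ± 26.6 FPKM in Cre cells, was listed at 0 in the 4 DTR libraries. Among the largest rises were Stmn1, a microtubule destabiliser (5.11 ± 2.56 to 47.6 ± 14.5 FPKM), Gfra2, the neurturin receptor (4.77 ± 1.79 to 29.7 ± 6.63 FPKM), and Ids, a lysosomal sulfatase (9.82 ± 1.91 to 56.2 ± 9.13 FPKM).

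In all, 3173 of 8871 genes passed limma in sorted cells, 1676 higher and 1497 lower, and after median centring 1881 were higher and 2124 lower. With quantile normalization 2596 were higher and 1860 lower, without DTR libraries 3 and 4 the numbers were 2201 and 1029, and without DTR library 2 they were 1094 and 1483, so which direction holds more genes depended on the setting. The groups did not overlap for 33.5% of genes against 2.86% by chance. A filter of 5 FPKM left 1897 of 4362 genes past the test, and the macrophage and monocyte call ended after median centring (adjusted p = 0.175), quantile normalization (0.13) or length correction (0.16), as the type 2 call did after median centring (0.0618).

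**Figure D3:**
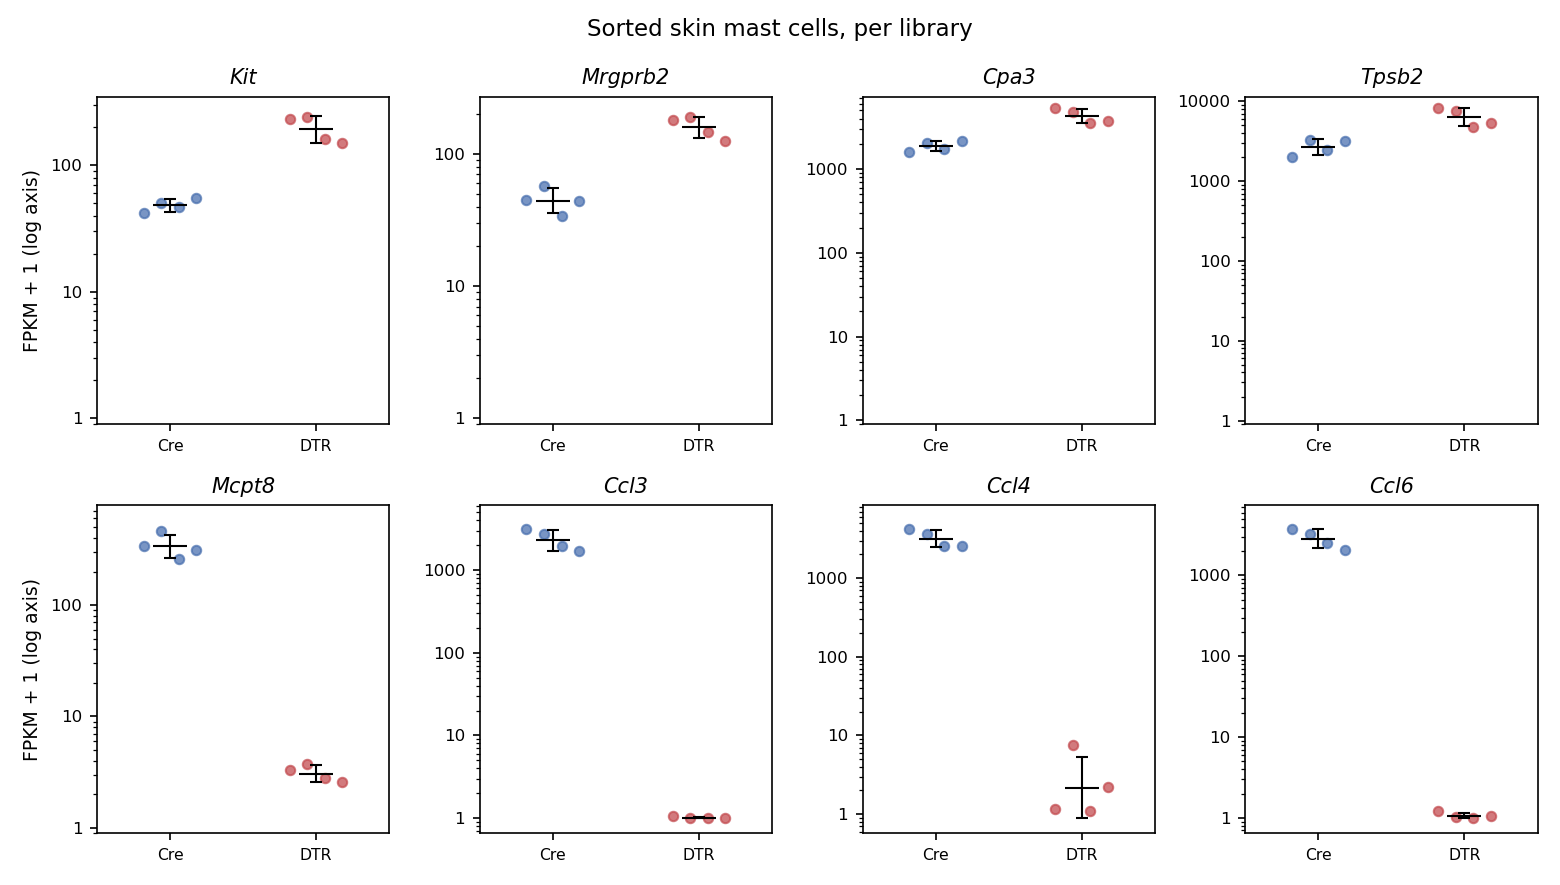
Each panel shows 1 gene in sorted skin mast cells as FPKM + 1 on a log axis, with points for the 4 Cre and 4 DTR libraries and a black bar for the mean ± SD of the log values. Kit averaged 47.6 FPKM in Cre and 196 FPKM in DTR cells, while Ccl3 averaged 2372 FPKM and 0.0116 FPKM.

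The ablation effect was set against itself in the other kind of sample. Of 13115 genes tested by the limma interaction, 3635 differed between sorted cells and skin, 1898 with the more positive change in sorted cells and 1737 with the more negative. Kit rose by more in sorted cells than in skin (difference of log2 changes 1.61, adjusted p = 4.51e-05), as did Mrgprb2 (1.43, adjusted p = 0.000242). Mcpt4 rose by less (-0.81, adjusted p = 0.0297). Ccl3 (log2 change 0.011 in skin and -11.15 in sorted cells) and Mcpt8 (-0.014 and -6.77) differed because they fell in sorted cells. Kit and Mrgprb2 lay at a few FPKM in skin, where the added 1 shrinks log2 changes, and Kit is also in the melanocyte list. By sex-linked genes the skin was female and the sorted cells male. The differences thus mix the kind of sample, the level of expression and sex.

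The fourth comparison asked what 4 mM glutamate did to cultured peritoneal mast cells in 6 h. Amino acid stress genes rose, and mast cell genes went both ways. Asns, asparagine synthetase and a target of the transcription factor ATF4 (chromosome 6, 7625170 to 7643182), rose from 5.12 ± 0.182 to 32.7 ± 2.13 FPKM (SD, n = 4 per group), and Tgm2, a transglutaminase, from 4.55 ± 0.174 to 57.5 ± 3.99 FPKM. Kit fell from 397 ± 35.8 to 191 ± 13.1 FPKM and Mrgprb2 from 87.6 ± 1.06 to 46.4 ± 2.89 FPKM, while Cpa3 rose from 8271 ± 187 to 12837 ± 490 FPKM and Tpsb2 from 38223 ± 1433 to 53601 ± 1177 FPKM. All genes together shifted by a median log2 of -0.33, and relative to that shift Asns changed by 2.79, Tgm2 by 3.72, Kit by -0.72, Mrgprb2 by -0.58, Cpa3 by 0.96 and Tpsb2 by 0.82, with limma adjusted p from 3.84e-13 (Tgm2) to 4.70e-08 (Tpsb2). Mcpt4 went from 813 ± 33.6 to 1115 ± 37.1 FPKM and Cma1 from 17362 ± 432 to 20709 ± 619 FPKM. With quantile normalization the log2 change of Cma1 turned to -0.26 and those of Cpa3 and Tpsb2 to 0. That setting gives each library the same value at each rank, so only a move in rank shows as a change. Tpsb2 was the most abundant gene in every library of this comparison, so its 0 was fixed in advance and does not bear on its rise.

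Of 22 amino acid starvation and ATF4 genes 17 rose and 2 fell, 17 and 2 adjusted over the list alone. Slc3a2, a subunit of amino acid exchangers, rose from 105 ± 3.33 to 219 ± 6.25 FPKM (SD, n = 4 per group). The list's median was 0.83 relative to all genes (camera adjusted p = 3.97e-11, adjusted p = 0.205 with an estimated correlation). Of 16 cytokine and chemokine genes 12 rose and 0 fell, 12 and 0 adjusted over the list alone, as in Ccl2, a monocyte chemokine (607 ± 16.1 to 871 ± 24.6 FPKM), and Ccl3 (14.4 ± 1.11 to 24 ± 2.09 FPKM). For this list the camera adjusted p was 2.22e-07, against adjusted p = 0.0538 with an estimated correlation. Of 25 ribosomal protein genes 22 rose, 23 adjusted over the list alone, as in Rpl3 (414 ± 6.14 to 524 ± 6.3 FPKM) and Rplp0 (630 ± 30.9 to 857 ± 16.6 FPKM). For ribosomal protein genes the camera adjusted p was 3.85e-13, against adjusted p = 0.403 with an estimated correlation and 0.297 with quantile normalization. Of 18 immediate early genes 11 rose and 4 fell, 11 and 4 adjusted over the list alone, with Junb up (57.1 ± 1.69 to 104 ± 3.6 FPKM) and Ier3 down (340 ± 13.1 to 103 ± 1.39 FPKM). Camera gave adjusted p = 4.42e-05 for the list, and adjusted p = 0.403 with an estimated correlation. Of 26 mast cell list genes 10 rose and 13 fell, 10 and 13 adjusted over the list alone, and the list was not called (camera adjusted p = 0.225). Among those that fell were Slc18a2, the vesicular amine transporter (173 ± 9.41 to 66.1 ± 3.18 FPKM), and Ms4a2, a chain of the IgE receptor (165 ± 7.43 to 85.2 ± 3.34 FPKM).

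Camera called 4 more lists higher relative to the other genes, with members that went both ways as deposited. In cell cycle genes 9 of 27 rose and 11 fell, among them Rrm2 (9.15 ± 0.530 to 20.4 ± 0.594 FPKM, SD, n = 4 per group). In glutamate transport and metabolism 6 of 14 rose and 4 fell, with Slc38a2, a neutral amino acid transporter, at 7.79 ± 0.398 to 3.48 ± 0.178 FPKM. In oxidative phosphorylation 8 of 22 rose and 7 fell, with Atp5b at 198 ± 3.07 to 302 ± 1.71 FPKM, and in p53 targets 6 of 13 rose and 5 fell, with Cdkn1a, a cell cycle inhibitor, at 67.9 ± 1.73 to 105 ± 3.4 FPKM. These counts carry the shift of all genes. After median centring 19 rose and 3 fell in cell cycle genes, 9 and 2 in glutamate transport and metabolism, 17 and 0 in oxidative phosphorylation and 8 and 2 in p53 targets, and after length correction 19 and 3, 9 and 2, 15 and 3, and 8 and 3. Without these corrections and adjusted over the list alone the risers and fallers numbered 9 and 11, 6 and 4, 7 and 7, and 6 and 5. The lists' medians before the shift were -0.093, -0.12, -0.003 and 0.0022, and 0.23, 0.21, 0.33 and 0.33 relative to it, and the means of cell cycle and oxidative phosphorylation genes were -0.027 and 0.030. Camera adjusted p was 0.0217 for the first 3 and 0.0379 for p53 targets, with adjusted p = 0.49 for cell cycle and 0.459 for the other lists with an estimated correlation. With quantile normalization the calls of glutamate transport (adjusted p = 0.0639), oxidative phosphorylation (0.455) and p53 targets (0.106) ended. The p53 call also ended after median centring (adjusted p = 0.0663) and after length correction (adjusted p = 0.0645).

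Among the largest rises with glutamate were Hist1h2bc (101 ± 5.77 to 534 ± 34.9 FPKM, SD, n = 4 per group) and Hist1h2ao (292 ± 22.7 to 1312 ± 26.4 FPKM), histone genes whose close copies can share reads. Aqp8, a water and peroxide channel, rose from 0.945 ± 0.145 to 13.5 ± 1.18 FPKM and Arrdc4, an arrestin-domain gene induced by glucose signals, from 3.16 ± 0.341 to 30.5 ± 2.61 FPKM. Acsbg1, an acyl-CoA synthetase, fell from 13 ± 0.841 to 0.406 ± 0.156 FPKM, Tbxas1, thromboxane synthase, from 52.4 ± 1.55 to 7.23 ± 0.546 FPKM and Hrh4, the histamine H4 receptor, from 35.4 ± 0.957 to 5.06 ± 0.199 FPKM. In all, 6580 of 8297 genes passed limma. As deposited 1403 were higher and 5177 lower, so that 21.3% were higher, and after median centring 3126 were higher and 3116 lower, so that 50.1% were. A filter of 5 FPKM left 3962 of 4848 genes past the test, and the groups did not overlap for 74.3% of genes against 2.86% by chance.

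The fifth comparison asked what NS102, an antagonist of kainate-type glutamate receptors, did to the cultured mast cells in 48 h. Chemokine transcripts rose and those of dividing cells fell. Ccl1, a chemokine for Ccr8-bearing cells (chromosome 11, 81990167 to 81993314), rose from 9.29 ± 2.4 to 255 ± 24.9 FPKM (SD, n = 4 per group), Ccl3 from 1.57 ± 0.522 to 27.6 ± 2.51 FPKM and Ccl7 from 23 ± 0.988 to 133 ± 14.3 FPKM. Kit rose from 257 ± 32.1 to 416 ± 28.4 FPKM, Mrgprb2 from 24.1 ± 1.71 to 36.9 ± 1.26 FPKM, Mcpt4 from 210 ± 8.58 to 337 ± 36.9 FPKM and Cma1 from 12572 ± 518 to 18337 ± 900 FPKM, while Cpa3 was at 13113 ± 585 FPKM in controls and 11774 ± 1111 FPKM in treated libraries (adjusted p = 0.134). The log2 changes were 4.67 (SE 0.15, limma adjusted p = 4.71e-10) for Ccl1, 0.70 (SE 0.081, adjusted p = 9.48e-06) for Kit and 0.59 (SE 0.059, adjusted p = 2.70e-06) for Mrgprb2, with the 4 NS102 libraries above the 4 controls for each. Of 19 cytokine and chemokine genes 17 rose and 2 fell, the same numbers adjusted over the list alone, with a median log2 change of 1.2 (camera adjusted p = 1.37e-07, adjusted p = 0.017 with an estimated correlation). Tpsb2 went from 32259 ± 385 to 39499 ± 4105 FPKM (adjusted p = 0.0304), a call that ended with median centring (adjusted p = 0.0781) and in most fits with a library left out. Cpa3 fell with quantile normalization (-0.27, adjusted p = 0.005), with a shared spread (adjusted p = 0.0272) and without NS102 library 2 (-0.22, adjusted p = 0.0237).

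Of 22 cell cycle genes 19 fell, 19 adjusted over the list alone, as in Birc5, survivin (10.3 ± 1.3 to 0.169 ± 0.124 FPKM, SD, n = 4 per group), and Ccnb2, cyclin B2 (7.09 ± 0.998 to 0.0662 ± 0.0570 FPKM). The camera adjusted p of the list was 1.28e-07, with adjusted p = 0.231 with an estimated correlation. All 25 ribosomal protein genes fell, 25 adjusted over the list alone, as in Rpl32 (1966 ± 117 to 674 ± 75.2 FPKM) and Rplp0 (683 ± 29 to 261 ± 29.8 FPKM). Here camera gave adjusted p = 8.37e-11, and adjusted p = 0.344 with an estimated correlation. Of 22 oxidative phosphorylation genes 21 fell, 21 adjusted over the list alone, as in Atp5c1 (196 ± 8.18 to 104 ± 5.4 FPKM). For this list the camera adjusted p was 4.04e-07, against adjusted p = 0.29 with an estimated correlation. Fold changes followed transcript length (Spearman rho 0.411 over 8307 genes, which are not independent replicates), with a median of -0.33 among the shortest 25% of transcripts and 0.20 among the longest 25%. After correction for length the ribosomal protein and oxidative phosphorylation medians went from -1.12 and -0.58 to -0.78 and -0.33, and both lists were still called (adjusted p = 1.23e-09 and 0.000909).

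Sterol and oxidative stress genes rose. Of 22 cholesterol biosynthesis genes 18 rose and 2 fell, as in Fdps, farnesyl diphosphate synthase (17.8 ± 0.752 to 49.8 ± 2.57 FPKM, SD, n = 4 per group). Camera gave adjusted p = 4.75e-07 for the list, and adjusted p = 0.231 with an estimated correlation. Of 19 NRF2 targets 16 rose and 2 fell, as in Nqo1, a quinone reductase (9.54 ± 1.31 to 27.8 ± 1.01 FPKM). The camera adjusted p of the list was 2.57e-05, with adjusted p = 0.211 with an estimated correlation. Of 17 immediate early genes 15 rose and 1 fell, as in Klf2 (5.24 ± 0.841 to 50.7 ± 2.1 FPKM) and Junb (23.4 ± 1.85 to 59.8 ± 5.44 FPKM). Here camera gave adjusted p = 2.86e-05, and adjusted p = 0.211 with an estimated correlation. Of 27 mast cell list genes 15 rose and 6 fell, as in Tpsab1, a tryptase (68.9 ± 3.61 to 392 ± 51.4 FPKM), and Gzmb (223 ± 10.4 to 567 ± 40.1 FPKM). For this list the camera adjusted p was 0.0347, against adjusted p = 0.519 with an estimated correlation. In these 4 lists the same numbers rose and fell adjusted over the list alone. The mast cell call ended with median centring (adjusted p = 0.067) and also without NS102 library 2.

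Penk, the enkephalin precursor, rose from 1.17 ± 0.600 to 41.9 ± 4.72 FPKM (SD, n = 4 per group), Mt2, a metallothionein, from 6.6 ± 1.5 to 108 ± 6.49 FPKM, and Iqgap1, a scaffold of the cytoskeleton, from 6.83 ± 1.66 to 48.3 ± 11.4 FPKM. Gp5, a platelet glycoprotein, fell from 66.2 ± 3.42 to 5.06 ± 0.633 FPKM, Rapsn from 80.3 ± 3.74 to 8.21 ± 0.974 FPKM and Hist1h2ao from 126 ± 12.9 to 6.94 ± 1.5 FPKM. In all, 5902 of 8373 genes passed limma, 2579 higher and 3323 lower, and after median centring 3030 were higher and 3016 lower. The groups did not overlap for 64.4% of genes against 2.86% by chance. A filter of 5 FPKM left 3757 of 4929 genes past the test.

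**Figure D4:**
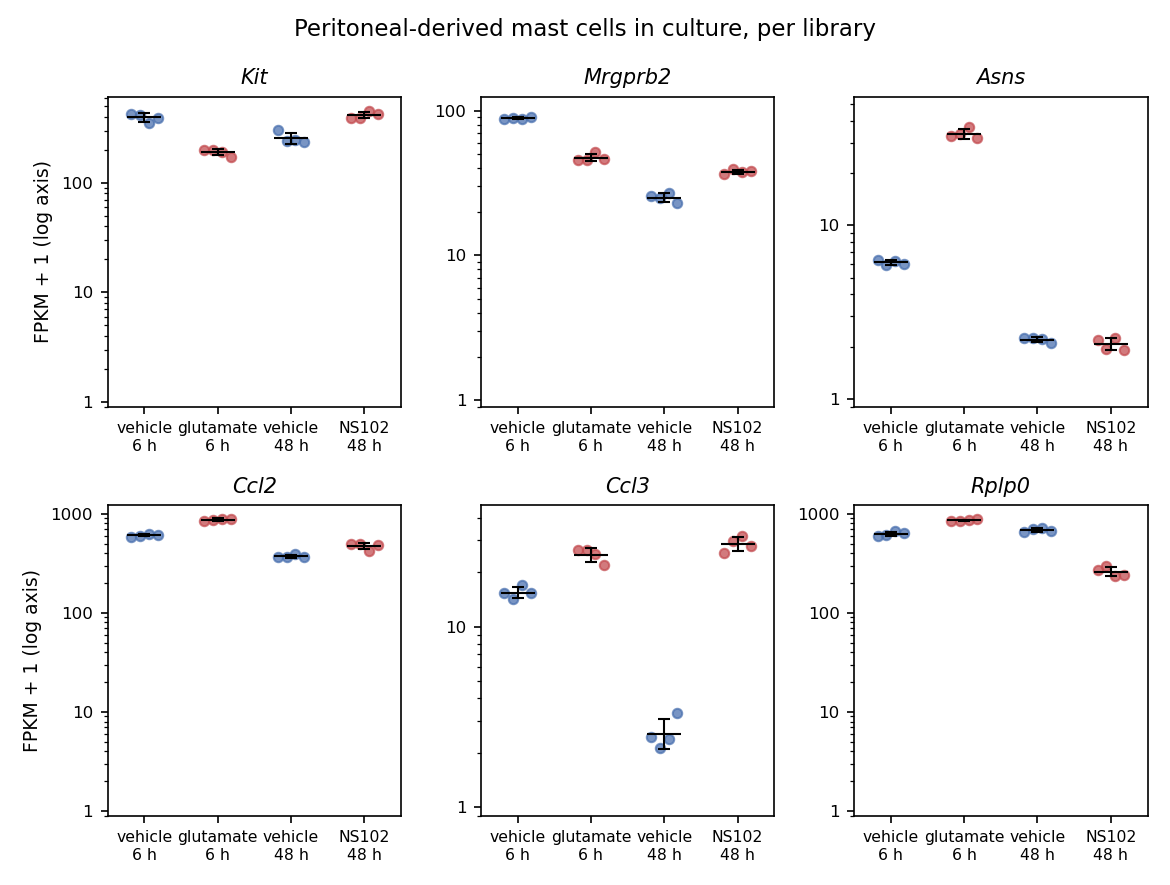
Each panel shows 1 gene in cultured mast cells as FPKM + 1 on a log axis, with points for the 4 libraries of each group and a black bar for the mean ± SD of the log values. Kit averaged 397 FPKM with vehicle and 191 FPKM with glutamate at 6 h, and 257 FPKM with vehicle and 416 FPKM with NS102 at 48 h.

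Pairs of comparisons were set against each other across genes, which are not independent replicates, in a family of 4 correlations. In skin, fold changes after ablation and after β-alanine ran in opposite directions over 12403 genes (Pearson r = -0.32, permutation p = 0.048, adjusted p = 0.192, Spearman rho = -0.246, permutation p = 0.039), a relation that did not pass after adjustment. Genes that rose after ablation and fell with β-alanine numbered 15 against 1.71 expected from the 2 counts, and 9 of them are mast cell list genes. The other 6 were Bcl6, Clec10a, Neat1, Rgs1, Serpinb1a and Zfp280d, singled out after their values were seen. Glutamate against NS102 gave r = -0.154 (permutation p = 0.462, adjusted p = 0.528, rho = -0.152, p = 0.479) over 7865 genes, with 675 genes up with glutamate and down with NS102 against 523 expected and 1583 the reverse against 1460. The culture times and media of these comparisons differ. Sorted cell ablation gave r = -0.038 against NS102 (permutation p = 0.528, adjusted p = 0.528, rho = -0.0427, p = 0.526) over 7687 genes and r = -0.117 against glutamate (permutation p = 0.18, adjusted p = 0.36, rho = -0.0984, p = 0.182) over 7577 genes. None of the 4 correlations passed after adjustment.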

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

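In this part the tests of explanations and the splits of the libraries were chosen only after the results had been seen, while the search for outlying libraries and the test of the ablation effect between sorted cells and skin were planned. The plot of sorted cells shows the first pattern. In sorted Cre libraries Mcpt8, Ccl3 and Cd7 were abundant and in DTR libraries close to 0, a candidate explanation being basophils among the sorted Cre cells. Of 17 basophil markers, settled and later extended after values had been seen, as was the criterion, 16 were tested, 12 were higher in Cre libraries and 1 (Cd200r4, 57.6 ± 6.17 to 134 ± 27.4 FPKM, SD, n = 4) in DTR libraries, with Prss34 at 42.7 ± 25.8 and 0.786 ± 1.34 FPKM and Itgb2 at 31.8 ± 7.94 and 0.148 ± 0.117 FPKM. Basophils and another state of the mast cells cannot be told apart, because the markers were chosen after these values had been seen, 8 of the 17 also reach 5 FPKM in cultured mast cells, the highest Cd3 value (2.15 FPKM) was above the 1 FPKM allowed for other cell types (highest of 5 eosinophil markers 0.522 FPKM), and the labels do not give the sort gate.

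A lower share of mast cells in the Cre libraries as the whole cause of the higher mast cell transcripts would change those of mast cells alone by 1 common factor. The log2 changes of Kit, Mrgprb2, Cpa3, Mcpt4, Cma1 and Tpsb2, genes named beforehand, had an SD among genes of 0.46 as deposited and 0.30 after correction for transcript length. The other splits of the libraries gave at most 0.318 and 0.229 (exact permutation p = 0.0286 for both, the smallest that 35 splits can give). This test replaced a ratio between mast cell genes grouped after their changes had been seen, and the changes of these 6 genes had also been seen, so the p-value is not independent of them. The spread argues against a lower share alone, while a partial role of it, other cells that carry some of these transcripts and an effect of the ablation on mast cells stay open.

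For the near absence of mast cell granule transcripts in β-alanine skin, scaling between libraries is excluded by the median log2 change of all genes (-0.044), and reads shared within the protease cluster of chromosome 14 as the whole cause by 6 mast cell genes elsewhere that fell (Cpa3, Gata2, Mrgprb1, Cyp11a1, Tpsb2 and Ms4a2, against 4 on chromosome 14). Animals of another genotype may be a source, since Sdr39u1, next to Cma1, was 2.07 times as high in β-alanine skin, while Khnyn (4.84 ± 0.267 to 4.45 ± 0.335 FPKM) and Atp12a (16.5 ± 1.69 to 16.2 ± 1.03 FPKM, SD, n = 4), also near the cluster, did not pass (adjusted p = 0.673 and 0.945). On chromosome 11, Psmc3ip fell in β-alanine skin (10.4 ± 0.792 to 4.34 ± 0.268 FPKM, limma adjusted p = 3.59e-05) by a step like that between Cre and DTR skin (11.3 ± 0.313 to 4.68 ± 0.265 FPKM), and Mcpt2 was at 138 FPKM in PBS skin against 0.00777 FPKM in Cre skin, groups not tested against each other. Genotype and treatment cannot be told apart here, because any difference between the animals would coincide with the treatment, and an effect of β-alanine on mast cells stays open and was not tested.

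With NS102, ribosomal protein and respiratory chain transcripts were lower. Scaling is excluded as the cause, since after median centring the higher of the medians of both lists was -0.53. Removing the trend of fold changes with transcript length moved the medians from -1.12 to -0.78 (SD over members 0.242 and 0.24) and from -0.58 to -0.33 (SD 0.256 and 0.295). The genes of these lists enter the fit of the trend, so this move cannot show whether the trend took part in the fall. The trend is excluded as the whole cause, since both lists were still called and the higher median was -0.33. An effect of NS102 or of fewer dividing cells stays open and was not tested.

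The ablation effect differed between sorted cells and skin by the interaction test for 54 of 64 named genes, given as the log2 change in sorted cells minus that in skin. Over all genes tested 3635 of 13115 differed. Many of the 64 were named for a large change in skin or in sorted cells, which by itself favours a difference. Where skin hardly changed, as for Ccl3 (log2 change 0.011), Cd7 (-0.0051) and Defb40 (0), the difference restates the fall in sorted cells. By sex-linked genes the skin was female and the sorted cells male, so sex differed along with the kind of sample. Genes that fell more in sorted cells had differences of -11.55 for Ccl6, -11.16 for Ccl3, -10.51 for Ccl4, -10.27 for Ifitm1, -8.33 for Ccl9, -8.20 for Cd7, -7.92 for Plac8, -7.14 for Niacr1, -7.05 for Defb40, -6.94 for Cyp4f18, -6.76 for Mcpt8, -6.33 for Alox15, -6.12 for Alox5ap, -6.05 for Pglyrp1, -5.22 for Slpi, -5.15 for Cdh1, -4.97 for Nfil3, -4.96 for Ccr2, -4.22 for Jund, -3.37 for Ccr3, -2.94 for Itgam, -2.37 for Rps19, -2.34 for Siglec5, -1.49 for Rpl8 and -1.21 for Rplp0. Genes that rose more there had differences of 2.96 for Nrip3, 2.83 for Stmn1, 2.56 for Fam129b, 2.44 for Ids, 2.21 for Slc30a2, 2.17 for Atp6v0d2, 2.11 for Olfr915, 2.03 for Gfra2, 1.99 for Esyt3, 1.93 for Clec12b, 1.61 for Kit, 1.43 for Mrgprb2, 1.40 for Ccnb2 and 1.14 for Mcm2.

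Genes that rose in skin and not in sorted cells had differences of -1.28 for Ccl20, -1.18 for Alad, -1.13 for Serpinb6d and -1.04 for Neat1, and Mcpt4, which rose in both, of -0.81. Genes that fell in skin, among them fat and muscle genes that sorted cells hardly express, had differences of 2.48 for Cyp2g1, 2.08 for Pvalb, 1.90 for Myh4, 1.86 for Nnat, 1.53 for Actc1, 1.34 for Myoz1, 1.27 for Adipoq, 1.22 for Lars2, 1.15 for Fabp4 and 0.88 for Actn3. The test called 3635 genes, and 2 of 100 splits of the 16 libraries gave as many, the highest other 3667. That split is 1 of 4 that kept the sorted groups apart and moved skin libraries only (3221 to 3667 genes), while the other 95 gave at most 52. This points to a structure of the samples: the count rests on the change in sorted cells, not on that in skin. The 95 splits mixed the sorted groups and so put their large change into the spread, from which low counts follow. They bear on the change in sorted cells alone and do not test whether the effect differs between sorted cells and skin.

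Of 328 gene and group combinations among the named genes, 18 (5.49%) had a library far from the other 3 by Dixon's criterion, where chance gives about 1 in 20. In skin these were Nnat in Cre skin library 2 (9.2 FPKM, the others 17.8 to 19.2) and Actn3 in DTR skin library 3 (1.82 FPKM, the others 3.2 to 3.38). In sorted cells they were Clec12b in sorted Cre library 4 (3.25 FPKM, the others 13.2 to 14), Ccl3 in sorted DTR library 1 (0.0466 FPKM, the others at 0), Cd7 in sorted DTR library 4 (0.126 FPKM, the others at 0), Plac8 in sorted DTR library 3 (0.0948 FPKM, the others at 0), Defb40 in sorted Cre library 3 (94.2 FPKM, the others 144 to 149), Alox15 in sorted DTR library 3 (0.0451 FPKM, the others at 0), Itgam in sorted DTR library 2 (0.111 FPKM, the others 0.0113 to 0.0255) and Cdh1 in sorted DTR library 2 (0.353 FPKM, the others 0.00679 to 0.0516). In cultured cells they were Fbxo9 in glutamate library 4 (1.46 FPKM, the others 1.65 to 1.69), Tspan32 in 6 h vehicle library 3 (34.5 FPKM, the others 33.1 to 33.3), Tspan32 in glutamate library 3 (6.66 FPKM, the others 5.62 to 5.74), Mrgprb2 in glutamate library 3 (50.7 FPKM, the others 44.6 to 45.4), Ccl1 in 48 h vehicle library 3 (5.71 FPKM, the others 10.1 to 10.8), Penk in NS102 library 3 (34.8 FPKM, the others 43.6 to 44.7), Kit in 48 h vehicle library 1 (305 FPKM, the others 236 to 245) and Junb in 48 h vehicle library 1 (26.2 FPKM, the others 22.2 to 22.8).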

How the results depend on the processing

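Here the length correction, median centring of the lists and the fits without DTR sorted libraries 3 and 4 or NS102 libraries 3 and 4 were chosen after seeing the data, and the other alternatives were planned. Counts of genes past the test moved by over 1.5 times for skin ablation (1719) with a shared spread (729), for β-alanine (27) with library weights (46) or a shared spread (130), and with a filter of 5 FPKM, which leaves fewer genes to test, for sorted cells (3173 to 1897), glutamate (6580 to 3962) and NS102 (5902 to 3757). Lists called numbered, with an estimated correlation and with fry, 0 and 2 for skin ablation (6), 1 and 3 for β-alanine (11), 1 and 13 for sorted cells (8), 0 and 16 for glutamate (8) and 1 and 15 for NS102 (8). Quantile normalization gave 10 lists for skin ablation and 5 for glutamate. The correlation of ablation with β-alanine (-0.32) lost p under 0.05 with a filter of 5 FPKM (-0.29, p = 0.0809) and a pseudocount of 5 (-0.31, p = 0.0709). Cma1 with glutamate reversed with quantile normalization (-0.26), a setting in which only ranks count. The cause of the other changes was not tested, apart from the filter.

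With each library left out, counts ranged from 779 to 1530 for skin ablation (947 without Cre library 4, 870 without DTR library 1, 779 without DTR library 2, 996 without DTR library 3), 20 to 38 for β-alanine, 2577 to 3662 for sorted cells, 6412 to 6527 for glutamate, 5495 to 5807 for NS102 and 3083 to 4374 for the interaction. Lists called ranged from 6 to 8, 7 to 16 (7 without PBS library 1), 8 to 9, 8 to 8 and 7 to 8. Correlations ranged from -0.367 to -0.26 for ablation with β-alanine, -0.171 to -0.131 for glutamate with NS102, -0.0474 to -0.0201 for sorted cells with NS102 and -0.127 to -0.103 for sorted cells with glutamate. The first lost p under 0.05 in 12 of 16 cases: without Cre library 2 (-0.305) or 3 (-0.317), DTR library 1 (-0.33), 2 (-0.316), 3 (-0.308) or 4 (-0.305), PBS library 1 (-0.316), 3 (-0.306) or 4 (-0.266), and β-alanine library 1 (-0.26), 3 (-0.293) or 4 (-0.29).

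Replicate numbers did not pair the libraries (residual correlations of same-number libraries from -0.25 to 0.37), and as a block they gave 1507, 20, 3272, 6629 and 5642 genes and 3833 for the interaction. Length correction gave 1447, 29, 4192, 6260 and 5903 genes, and fits without libraries 3 and 4 gave 3230 for sorted cells and 5310 for NS102. The setting meant for counts was not run, since the table holds FPKM. Depth is unknown, so values near 0 FPKM carry no stated limit.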

Other observations

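In this part the values and tests on sex-linked genes, on splits of the libraries and on the correlation without mast cell genes were chosen only after the results had been seen. Cre and DTR skin expressed Xist (26.9 ± 3.11 and 34.6 ± 1.84 FPKM, SD, n = 4) and listed Ddx3y at 0, whereas PBS and β-alanine skin expressed Ddx3y (15.4 ± 0.712 and 15.6 ± 3.2 FPKM), as did sorted Cre and DTR cells (6.35 ± 1.85 and 6.5 ± 1.6 FPKM). The skin and the sorted cells of the ablation comparisons thus came from animals of different sex, and sex did not differ within any comparison. The cultured cells expressed Xist (2.03 ± 0.137 FPKM with vehicle at 48 h) and listed Ddx3y at 0.

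In β-alanine skin, Iigp1, an interferon-induced GTPase, went from 1.28 ± 0.231 to 4.08 ± 1.47 FPKM (limma adjusted p = 0.0433), and Neat1, which rose after ablation, fell from 262 ± 21.9 to 147 ± 14.2 FPKM (adjusted p = 0.00234). Hdc, the enzyme that makes histamine, was at 2.13 ± 1.12 FPKM in PBS and 0.449 ± 0.339 FPKM in β-alanine skin (adjusted p = 0.149). Grik2 in sorted cells, below the expression filter and not tested, was at 0.319 ± 0.255 FPKM in Cre and 0.95 ± 0.168 FPKM in DTR libraries, and in cultured cells at 0.276 ± 0.036 FPKM with vehicle and 0.507 ± 0.056 FPKM with glutamate.

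Without the mast cell list, the correlation of fold changes between ablation and β-alanine in skin was -0.283 (permutation p = 0.0799), against -0.32 with it. The remaining r lay within the spread of relabelled libraries (95% of absolute r under 0.316 over all genes), so whether mast cell transcripts are the whole cause cannot be told apart from other sources here.

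In each of the 5 comparisons 1 of 35 splits of the 8 libraries, the real split, gave as many genes. This argues against chance as the source of the counts, though 35 splits allow no smaller share. Splits cannot tell a treatment from any other difference between samples that follows the groups. The real counts and the highest of the other splits were 1719 and 1 for skin ablation, 27 and 12 for β-alanine, 3173 and 5 for sorted cells, 6580 and 0 for glutamate and 5902 and 0 for NS102.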
